A study of Drosophila melanogaster with 74 samples.

How the data were processed

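Gene expression was profiled by shallow RNA sequencing of polyadenylated RNA from pooled brains of Oregon wild-type Drosophila melanogaster, with 100 brains in each library, per the labels' protocols. The submitters' processing notes list UMI-tools 1.1.2, Trimmomatic 0.39, STAR 2.7.10a, HTSeq 2.0.1 and edgeR 3.36.0. The role and order of these tools, and the genome build, are not given in the sources used here.

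The authors deposited 1 table of normalized values, with 13160 gene rows and 71 columns of per-library values. None of its 71 columns was assigned to a sample. The columns are named by bare numbers from 2 to 74, and no title, description or characteristic gives a library such a number. The numbers 1, 14 and 45 are absent. The 3 libraries marked as outliers removed from analysis hold places 1, 14 and 45 when the 74 samples are listed in accession order, which is 1 of 64824 possible sets of 3 places. The column numbers are therefore very probably places in that list. This link rests on the order of samples and on no label of a single column, and group membership was not taken from the order of samples, accessions or columns, nor from expression values. By that rule all 71 columns were left out, and no depth, expression level, fold change or test was computed from the table.

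Libraries were assigned to groups from their titles, by sex, day and dose. The comparisons fixed before the data were examined set each dose against the untreated flies of the same sex and day, with limma on log2 values as the test. They also covered the shape of the dose response, the interactions of dose with sex and with duration, and the sex and age differences among untreated flies. None of these comparisons was run, under any setting.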

Results

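The series profiled brain gene expression in Drosophila melanogaster fed hexafluoropropylene oxide dimer acid (HFPO-DA), a per- and polyfluoroalkyl substance used in making fluoropolymers. Its title names a non-monotonic dose response, which was not tested here. Virgin females and males were kept apart from eclosion and received the compound in their food at 10, 100 or 1000 mg/kg/day, or untreated food, until day 3, 7 or 14.

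The labels place 74 libraries in 24 groups, from 2 sexes, 3 durations, and 3 doses with a control. Of these groups, 23 held 3 libraries each. The remaining group, females given 10 mg/kg/day for 3 days, held 5 libraries. The submitters marked 3 libraries as outliers removed from analysis. They were 2 of the 5 libraries from females given 10 mg/kg/day for 3 days and 1 of the 3 libraries from females given 1000 mg/kg/day for 14 days. The other 71 libraries left 3 in the first of these groups and 2 in the second, so that 23 of the 24 groups had at least 3 libraries.

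No expression comparison between doses, sexes or durations was made, because no column name of the deposited table is a label of a library, and groups were not assigned from sample order. Levels of individual genes, their spread between replicate pools and the depth of each library were not analysed here.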

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

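No expression result was computed, so none was tested for its dependence on the processing. The only values compared between settings are counts of libraries taken from the labels. These counts were added after the data were examined and test nothing about gene expression. With the libraries marked as outliers left out, 71 libraries remained and 23 groups had at least 3. With them kept, the counts were 74 libraries and 24 groups. The settings fixed before the data were examined (pseudocount, filter, scaling, weights, outlier libraries kept in the expression tests, the fit to one sex and day alone, tests on recovered reads, single replicates left out) were not run.

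No paired analysis was possible under the rule followed here, because that rule takes no column's library from sample order. The fit was declined by that rule and was not shown to be infeasible. The labels number the replicates and do not say that a number links libraries of different groups.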
